A study of Homo sapiens with 12 samples.

How the data were processed

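RNA sequencing was done on 12 libraries of A172 cells, 4 with a scrambled control siRNA, 4 with siRNA-1 and 4 with siRNA-2 against uc.110. Per the labels, cells were seeded in 6-well plates and transfected on day 1 for 6 h with 3 µL of 20 µM siRNA and 9 µL of a Lipofectamine reagent, and total RNA was collected on day 2 after transfection with a column kit. The siRNA sequences are not given in the sources used here. The deposited table holds raw whole-number counts of reads per interval, with no normalization, for 49731 intervals: genes of the CHESS and RefSeq annotations, 481 ultraconserved regions and 481 random control regions. The authors name Salmon and the hg38 build in their processing notes, without a version or a setting, and the tool that made the interval counts is not given in the sources used here.

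The counts were checked for what they hold. Intervals cover whole gene spans and overlapping intervals share reads whatever their strand: in 2702 nested pairs on the same strand and 3699 on opposite strands, with at least 120 reads in the inner interval, the outer count was never below the inner one. Overlaps are therefore given for genes named singly where they hold a large share of the reads. The start or end equalled that of the GRCh38 reference for 61.5% of matched genes. Left out were 962 regions and 3660 gene intervals: 2063 that reach over 100 kb beyond the gene of that name, 45 without a match and over 1 Mb long, 28 with a number for a name, 1025 under an older name of a gene that has its own interval, 449 with the same counts as another interval in all libraries, 31 of ribosomal RNA and 19 copies on chromosome Y. This left 45109 gene intervals, of which 19240 were protein-coding and 8668 had no match in the reference. Genes of the lists lost this way were NKD2, LRP6, WNT3, SESN2, IFI27, IRF7, IRF9, IER3, HYOU1, LSS, GPI, ID3, HES5, PTPRC, AIF1 and MOG. The 45S ribosomal RNA stretch was taken as chromosome 21, 8205988 to 8446572.

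Genes were tested with edgeR 4.0.16 (R 4.3.3), with TMM normalization, filterByExpr (minimum count 10, minimum total 15), a robust quasi-likelihood fit of all 12 libraries with group as the only term, and two-sided tests adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were siRNA-1 against scrambled, siRNA-2 against scrambled, the mean of both against scrambled, and siRNA-2 against siRNA-1. SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM uses TMM-scaled library sizes. The ratios for uc.110 and MFRP come from a two-sided exact Poisson test of summed counts with library size as offset and 95% intervals.

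The comparisons, tests, gene lists, alternatives and naming rule were fixed before the data were examined. In each comparison with scrambled, the rule names genes past the threshold whose siRNA libraries all lie on 1 side of all scrambled libraries: the 8 highest and 8 lowest fold changes (average log2 CPM at least 1) and the 5 smallest p-values in each direction (at least 4). It names the 5 highest and 5 lowest between the siRNAs, the 8 highest and 8 lowest by the smaller change of both siRNAs, up to 4 members of each list by p, MFRP, and any gene that holds uc.110. The text gives a part of the genes so named, and some are not reported here. Camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison) tested 18 lists against all other genes: type I interferon response, G2/M and mitosis, G1/S and DNA replication, hypoxia and glycolysis, extracellular matrix and mesenchymal, epithelial marker, cholesterol synthesis, Wnt/beta-catenin target, Wnt ligands, receptors and regulators, p53 target, NF-kB and cytokine, ATF4 and unfolded protein response, TGF-beta and YAP target, neural stem cell and glial, RNA interference machinery, apoptosis, hematopoietic and endothelial marker, and neuron and oligodendrocyte marker genes. A list of 13 mitochondrially encoded genes had no interval.

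Tested on simulated data with changes planted in siRNA-1 against scrambled, the test recovered 39 of 50 genes at 1.5-fold, 50 of 50 at 2-fold and 50 of 50 at 4-fold, and called 12 of 24737 unchanged genes. Changes were planted only in genes with average log2 CPM of at least 1, so recovery at lower counts was not tested. The alternatives set in advance were the factors of DESeq2 in edgeR, DESeq2 1.42.0 itself, no filter, a filter of 1 CPM in at least 4 libraries, only the groups compared, a replicate block, leaving out each library, camera with an estimated correlation, and fry. Sequence words were searched in annotated 3' UTRs of 11772 of 12401 protein-coding genes with average log2 CPM of at least 1, with 100 shuffles as the bound. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.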

Results

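The transcriptome of A172, an established human glioblastoma cell line, was measured to find genes whose level changes after siRNAs against uc.110. uc.110 is 1 of 481 ultraconserved elements, stretches of genome that human, mouse and rat share without a difference and some of which are transcribed. Cells received a scrambled control siRNA, siRNA-1 against uc.110 or siRNA-2 against uc.110, and RNA was collected on day 2 after transfection. Each of the 3 groups held 4 libraries, 12 in all, with 42758609 to 52925535 counts per library over the 45109 gene intervals used. The share of reads in 45S ribosomal RNA intervals lay between 1.88% and 5.55% in 10 libraries, and was 15.9% in siRNA-1 replicate 3 and 9.28% in siRNA-2 replicate 2. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. All log2 fold changes below come from 4 libraries against 4.

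Reads at the targeted region were few. uc.110 lies on chromosome 2, from 236162738 to 236162980 (hg38), and is listed as intergenic. It held 4, 0, 1 and 6 reads in the scrambled libraries, 2, 0, 1 and 2 with siRNA-1, and 3, 0, 4 and 0 with siRNA-2. The summed counts of 11, 5 and 7 gave a ratio to scrambled of 0.459 for siRNA-1 (95% interval 0.125 to 1.43, exact two-sided Poisson ratio test p = 0.21) and 0.595 for siRNA-2 (0.196 to 1.68, exact p = 0.348). These intervals cover counting error only, and a difference in uc.110 was not detectable at this depth. LOC105373944, on the minus strand of chromosome 2 from 236161340 to 236164886, holds uc.110 within its span. It had 17 to 40 reads in the scrambled libraries, 12 to 22 with siRNA-1 and 9 to 16 with siRNA-2. Its log2 fold change was -0.68 (SE 0.32, adjusted p = 0.0793, and adjusted p = 0.0317 without scrambled replicate 3) with siRNA-1, and it fell by 1.24 (SE 0.33, adjusted p = 0.00263) with siRNA-2. Scrambled replicate 3 had the lowest scrambled count, 17, so leaving it out raises the control mean. The highest, 40, was in scrambled replicate 1. That library also had reads in 1667 intervals that no other library covered, against 89 to 176 such intervals in each of the others, so its low counts call for caution. MFRP, a membrane frizzled-related protein gene on chromosome 11 from 119338935 to 119346705, held 1 read over the 4 scrambled libraries, 4 with siRNA-1 and 6 with siRNA-2, which was too few for the test across genes. The ratios were 4.04 (95% interval 0.4 to 199, exact p = 0.216) and 5.61 (0.681 to 258, exact p = 0.126).

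**Figure D1:**
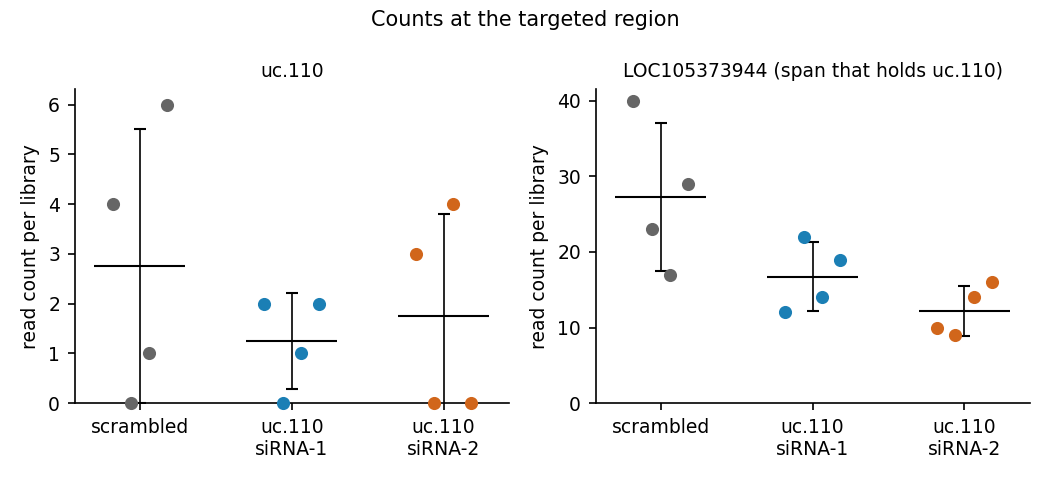
Reads per library (vertical axes, counts) in uc.110 and in LOC105373944 for the 3 groups. Points are libraries, horizontal lines are group means and bars are SD (n = 4), drawn no lower than 0. uc.110 held 0 to 6 reads per library, and LOC105373944 held 17 to 40 with scrambled siRNA and 9 to 16 with siRNA-2.

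The first comparison, siRNA-1 against scrambled, asks which genes differ after that siRNA. Interferon-stimulated genes were among the most raised. XAF1, a proapoptotic interferon-induced gene on chromosome 17, went from 2.72 ± 1.68 CPM (SD, n = 4) to 38.1 ± 4.34 CPM, a log2 fold change of 3.82 (SE 0.27, adjusted p = 1.08e-06). LGALS9, which encodes galectin-9, rose by 3.57 (SE 0.19), LAMP3 by 3.27 (SE 0.17), SECTM1 by 3.21 (SE 0.09) and ZBP1, a sensor of Z-form nucleic acid, by 3.04 (SE 0.27), or 3.65 without scrambled replicate 1. ISG15, a ubiquitin-like modifier gene whose interval overlaps CHESS3, rose by 2.93 (SE 0.24) and IFITM1, an inhibitor of virus entry, by 3.11 (SE 0.27), although the IFITM1 interval lies inside LOC101059906 and shares its reads. CHRNA1, a subunit of the muscle acetylcholine receptor, rose by 3.21 (SE 0.18).

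Among genes lowered by siRNA-1, GPAT3, which encodes an enzyme of triglyceride synthesis, went from 6.57 ± 0.85 to 1.41 ± 0.47 CPM, a log2 fold change of -2.21 (SE 0.17, adjusted p = 1.79e-10). CNTN1, a neural cell adhesion gene, had a log2 fold change of -2.19 (SE 0.09), SYTL5 of -2.05 (SE 0.11), THSD7A of -2.04 (SE 0.13) and LCP1, which encodes an actin-bundling protein, of -2.01 (SE 0.11). ROR1, a receptor for WNT5A on chromosome 1, had a log2 fold change of -2.15 (SE 0.10), with the same value for its antisense gene ROR1-AS1, whose reads cannot be told apart from those of ROR1. SNORA26 lies inside LOC107986280 and had a log2 fold change of -2.04 (SE 0.16). Among more abundant genes the smallest p-values belonged to IGFBP5, an insulin-like growth factor binding protein gene (2.00, SE 0.04, adjusted p = 5.06e-21), HIPK3 (1.58, SE 0.04), MATN2 (1.65, SE 0.05), and NFASC (1.24, SE 0.04) on the raised side, with CPA4, which shares reads with LOC105375503, at 70.0 ± 5.48 CPM and 198 ± 2.90 CPM. On the lowered side they belonged to SH3KBP1 (-1.42, SE 0.04, adjusted p = 3.3e-19), SVIL (-1.20, SE 0.04, overlapping SVIL-AS1), CEMIP2 (-1.32, SE 0.04), the decoy receptor gene TNFRSF11B (-1.79, SE 0.06) and HADHA (-1.48, SE 0.05), a mitochondrial fatty acid oxidation gene whose interval overlaps GAREM2.

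Of 24937 genes tested, 13318 differed with siRNA-1, 7123 higher and 6195 lower, and 15038 of those tested were protein-coding, of which 5262 were higher and 4212 lower. The balance of higher and lower genes was not the same in every fit: in a fit of protein-coding genes only, 4779 were higher and 4865 lower. The median size of the called changes was 0.42 on the log2 scale, and 1861 genes changed at least 2-fold, 1275 upward and 586 downward. The 4 libraries of siRNA-1 lay on one side of all 4 scrambled libraries for 47.4% of genes, where chance gives 2.86%.

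Of the gene lists fixed in advance, 7 passed with siRNA-1. All 25 tested type I interferon response genes rose, with a median log2 fold change of 2.00 (camera adjusted p = 2.4e-17, and adjusted p = 0.376 with an estimated correlation). IFIT2 rose by 1.46 (SE 0.07), the antiviral GTPase gene MX1 by 0.87 (SE 0.07), ISG20 by 2.48 (SE 0.12) and IFIH1, which encodes the RNA sensor MDA5, by 1.68 (SE 0.11). IFIT2 lies inside LOC105378419. In scrambled replicate 1 all 25 of these genes had the highest level among the scrambled libraries, by a median of 1.94 times the mean of the other 3. Of 25 G2/M and mitosis genes, 22 fell and 1 rose (camera adjusted p = 8.51e-09, and adjusted p = 0.431 with an estimated correlation). TOP2A, the mitotic topoisomerase gene, fell by 0.82 (SE 0.04), CENPF by 0.60 (SE 0.04) and TPX2 by 0.54 (SE 0.04). Of 25 G1/S and DNA replication genes, 18 fell and 1 rose (adjusted p = 5.27e-04, and adjusted p = 0.489 with an estimated correlation), with a log2 fold change of -0.44 (SE 0.04) for RRM1, which encodes a ribonucleotide reductase subunit.

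Hypoxia and glycolysis genes were higher with siRNA-1, 16 of 22 up and 3 down (adjusted p = 5.15e-05, and adjusted p = 0.254 with an estimated correlation). The aldolase gene ALDOC rose by 2.30 (SE 0.12) and P4HA2, a collagen prolyl hydroxylase gene that shares reads with P4HA2-AS1, by 0.81 (SE 0.03). Extracellular matrix and mesenchymal genes had 16 of 26 up and 4 down (adjusted p = 7.48e-04, and adjusted p = 0.489 with an estimated correlation). In this list COL1A1 rose by 1.80 (SE 0.05), while VIM, which overlaps VIM-AS1, fell by 0.64 (SE 0.04). Epithelial marker genes had 8 of 13 up and 1 down (adjusted p = 0.00184, and adjusted p = 0.261 with an estimated correlation), with the overlapping keratin genes KRT8 and KRT18 raised by 1.07 (SE 0.04) and 0.93 (SE 0.04). This call was lost among genes that overlap no other tested gene (adjusted p = 0.628). Cholesterol synthesis genes had 15 of 22 up and 4 down (adjusted p = 0.0128, and adjusted p = 0.489 with an estimated correlation), for example MSMO1, up by 0.69 (SE 0.04). Without scrambled replicate 1 the adjusted p of this list was 0.0806, and among genes that overlap no other it was 0.421.

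The other 11 lists did not pass with siRNA-1. Wnt ligands, receptors and regulators had 16 of 34 up and 7 down (camera adjusted p = 0.216, and adjusted p = 0.0221 among genes that overlap no other), with WNT5A up by 0.91 (SE 0.04), the receptor gene FZD2 up by 0.98 (SE 0.04) and ROR1 down. Wnt/beta-catenin target genes had 7 of 17 up and 5 down (adjusted p = 0.78), with the Wnt antagonist DKK1 up by 0.58 (SE 0.04) and CCND1, which encodes cyclin D1, down by a log2 fold change of -0.67 (SE 0.04). The counts up and down were 7 and 8 of 22 for p53 target genes (adjusted p = 0.588), 5 and 6 of 15 for NF-kB and cytokine genes (0.261), and 14 and 2 of 22 for ATF4 and unfolded protein response genes (0.261). They were 9 and 6 of 17 for TGF-beta and YAP target genes (adjusted p = 0.341), 6 and 2 of 15 for neural stem cell and glial genes (0.319), 5 and 9 of 15 for RNA interference machinery genes (0.809) and 5 and 6 of 22 for apoptosis genes (0.588). Markers of other cell types had 1 up and 2 down of 10 for hematopoietic and endothelial marker genes (adjusted p = 0.588) and 3 and 3 of 11 for neuron and oligodendrocyte marker genes (0.906). Counts adjusted over the list alone were the same with siRNA-1, except 17 up for cholesterol synthesis genes and 6 up and 7 down for NF-kB and cytokine genes.

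**Figure D2:**
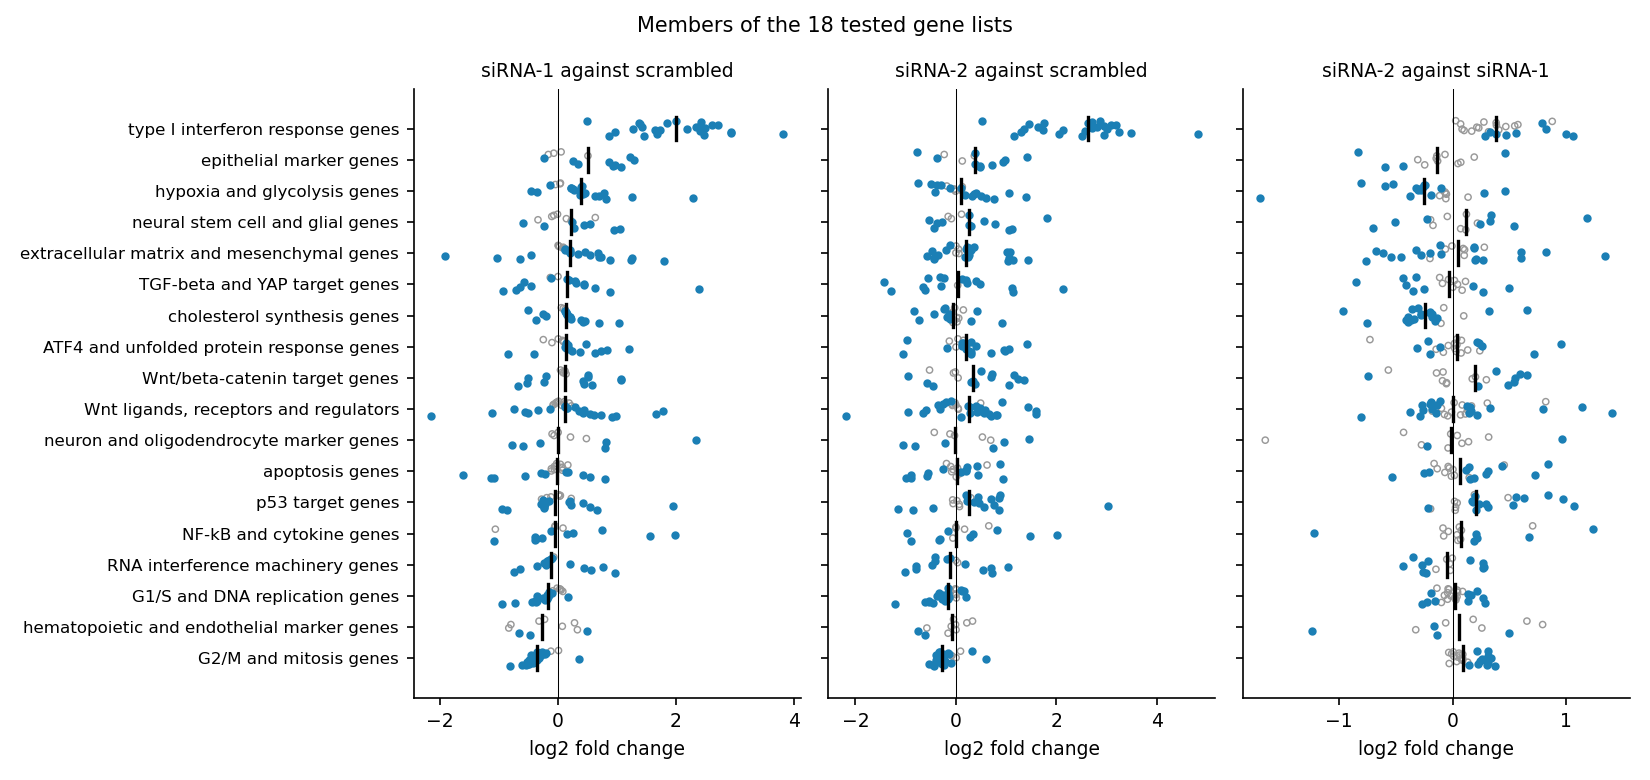
Log2 fold change (horizontal axes) of each tested member of the 18 lists in the 3 comparisons. Filled points passed the threshold, open points did not, and black bars are list medians. All 25 type I interferon response genes lie to the right of 0 in both comparisons with scrambled.

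The next comparison, siRNA-2 against scrambled, puts the same question with the other siRNA. XAF1 again led, at 76.3 ± 5.92 CPM against 2.72 ± 1.68, a log2 fold change of 4.82 (SE 0.27, adjusted p = 1.34e-07). ZBP1 rose by 4.16 (SE 0.25), or 4.78 without scrambled replicate 1, SECTM1 by 3.87 (SE 0.09), LAMP3 by 3.81 (SE 0.17), LGALS9 by 3.60 (SE 0.19) and OASL, an oligoadenylate synthetase-like gene, by 3.49 (SE 0.21). CD7, a T cell surface antigen gene next to SECTM1 on chromosome 17, rose by 3.70 (SE 0.20) from 0.29 ± 0.09 CPM to 3.78 ± 0.59 CPM. ABCA13, a lipid transporter gene, had a log2 fold change of -2.57 (SE 0.10, adjusted p = 1.23e-16), the aldo-keto reductase gene AKR1B10 of -2.42 (SE 0.15), the sorting receptor gene SORL1 of -2.39 (SE 0.14), and LMO1, a transcriptional cofactor gene whose interval overlaps LOC105376536, of -2.23 (SE 0.11). The noncoding gene LUCAT1 had a log2 fold change of -2.19 (SE 0.18), ROR1 of -2.19 (SE 0.10) and MAP2, a neuronal microtubule-associated protein gene, of -2.05 (SE 0.15).

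Among abundant genes raised by siRNA-2, PLAT, which encodes tissue plasminogen activator, went from 809 ± 32.3 to 3149 ± 155 CPM, a log2 fold change of 1.96 (SE 0.04, adjusted p = 4.24e-21). IGFBP5 rose by 1.77 (SE 0.04), THBS2 by 1.73 (SE 0.05, with an interval that overlaps LOC101929523) and the transcription factor gene LHX9 by 1.47 (SE 0.04). On the lowered side, WEE1, the mitosis-inhibiting kinase gene, went from 97.1 ± 5.74 to 32.0 ± 1.45 CPM, a log2 fold change of -1.60 (SE 0.05, adjusted p = 1.18e-18). PRKAR2A had a log2 fold change of -1.38 (SE 0.05), EIF4EBP2 of -1.18 (SE 0.04), TBC1D5 of -1.28 (SE 0.04) and SVIP, inside GAS2, of -1.55 (SE 0.06). In all, 13988 of 24937 genes differed with siRNA-2, 7468 higher and 6520 lower, of which 2181 changed at least 2-fold, 1592 upward and 589 downward. Among protein-coding genes 5279 were higher and 4585 lower, but 4972 and 5092 when these were fitted alone. The groups lay fully apart for 51.8% of genes, where chance gives 2.86%. The contrast of the mean of both siRNAs with scrambled called 14428 genes, 7623 higher and 6805 lower.

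With siRNA-2, 4 lists passed. All 25 type I interferon response genes rose, with a median log2 fold change of 2.63 (camera adjusted p = 5.33e-22, and adjusted p = 0.64 with an estimated correlation). IFIT2 rose by 2.52 (SE 0.07), ISG20 by 2.95 (SE 0.12) and ISG15 by 3.25 (SE 0.24). G1/S and DNA replication genes had 15 of 25 down and 4 up (adjusted p = 0.00383, and adjusted p = 0.64 with an estimated correlation), and G2/M and mitosis genes 20 of 25 down and 2 up (adjusted p = 0.00383, and adjusted p = 0.647 with an estimated correlation). MCM6, a subunit of the replicative helicase, fell by 0.61 (SE 0.04) and BIRC5, which encodes survivin, by 0.53 (SE 0.05), while KIF11, a mitotic kinesin gene, rose by 0.61 (SE 0.04). Extracellular matrix and mesenchymal genes had 15 of 26 up and 7 down (adjusted p = 0.0088, and adjusted p = 0.64 with an estimated correlation), with FN1, the fibronectin gene, at 97.8 ± 3.14 CPM with scrambled siRNA and 199 ± 7.82 CPM with siRNA-2. Without scrambled replicate 1 the adjusted p of this list was 0.0522.

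Of the lists that did not pass with siRNA-2, Wnt/beta-catenin target genes had 10 of 17 up and 3 down (camera adjusted p = 0.239), with DKK1 up by 1.06 (SE 0.04) and CCND1 down by a log2 fold change of -0.45 (SE 0.04). Wnt ligands, receptors and regulators had 18 of 34 up and 9 down (adjusted p = 0.239, and adjusted p = 0.013 among genes that overlap no other). p53 target genes had 13 of 22 up and 3 down (adjusted p = 0.239), with XPC, a nucleotide excision repair gene, up by 0.76 (SE 0.04). ADM, which encodes the vasodilator adrenomedullin, rose by 1.39 (SE 0.07). The counts up and down were 15 and 3 of 22 for ATF4 and unfolded protein response genes (adjusted p = 0.115), 10 and 6 of 22 for hypoxia and glycolysis genes (0.344), 3 and 9 of 22 for cholesterol synthesis genes (0.344) and 8 and 2 of 13 for epithelial marker genes (0.212). They were 5 and 5 of 15 for NF-kB and cytokine genes (adjusted p = 0.374), 8 and 8 of 17 for TGF-beta and YAP target genes (0.799), 8 and 4 of 15 for neural stem cell and glial genes (0.344), 5 and 8 of 15 for RNA interference machinery genes (0.365) and 8 and 6 of 22 for apoptosis genes (0.997). Hematopoietic and endothelial marker genes had 0 up and 2 down of 10 (adjusted p = 0.365), and neuron and oligodendrocyte marker genes 3 and 3 of 11 (0.799). Counts adjusted over the list alone were the same with siRNA-2, except 11 up for hypoxia and glycolysis genes and 9 up for epithelial marker genes and for neural stem cell and glial genes. The 13 mitochondrially encoded genes had no interval in the table.

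**Figure D3:**
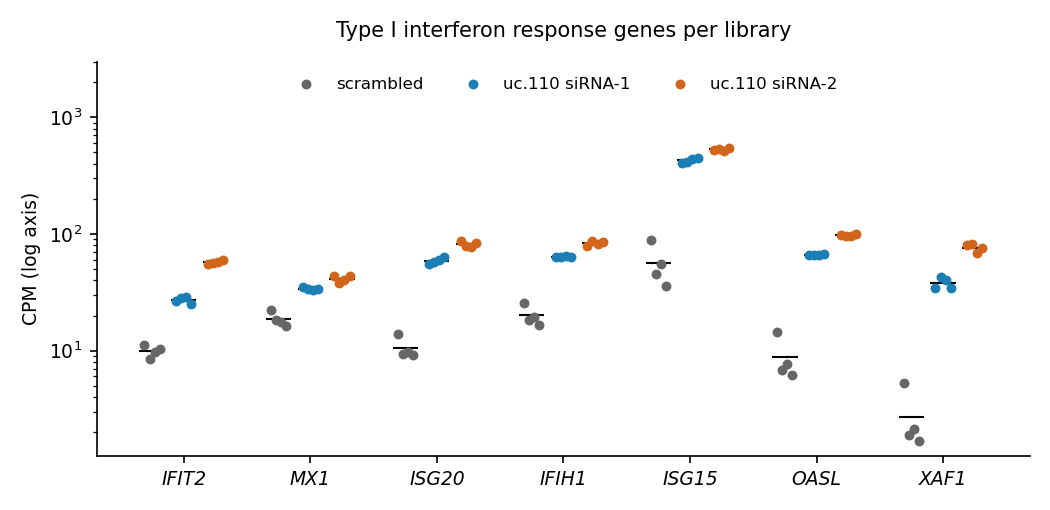
CPM per library (log axis) of 7 type I interferon response genes in the 3 groups. Points are libraries and lines are means (n = 4). ISG15 averaged 56.1 CPM with scrambled siRNA, 429 with siRNA-1 and 534 with siRNA-2.

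Both siRNAs called 10118 genes in the same direction, 5509 up and 4609 down, of which 1183 changed at least 2-fold in both, 928 up and 255 down. XAF1, LGALS9, LAMP3, SECTM1, IFITM1, ZBP1, ISG15 and OASL were raised most by both. ROR1, ROR1-AS1, AKR1B10, LUCAT1, MAP2, SNORA26, ABCA13 and DANCR, a noncoding gene in the same interval as SNORA26, were lowered most by both. DANCR had log2 fold changes of -1.76 (SE 0.09) and -1.86 (SE 0.09). Lists that overlapped independently would share 2133 genes up and 1620 down. In 20 simulations all 12 libraries, scrambled included, were drawn at the mean scrambled level of each gene, and 0 to 1 genes were shared. With no gene changed, few calls could arise there. No real scrambled library entered the simulations, so they do not carry the traits of a single control library. With the scrambled libraries divided 2 and 2 between the siRNAs, 8017 to 8550 genes were shared over the 6 assignments. Across the 24937 genes, which are not independent replicates, the fold changes of both siRNAs had a Pearson r of 0.806 and a Spearman rho of 0.779. The simulated mean r was 0.498 for unchanged groups that share their controls. With divided controls r was 0.573 to 0.642, over 26164 genes. The simulated values are no reference for divided controls, where the siRNAs share no control library. Their covariance was 0.309, against a simulated 0.0262, and 0.295 to 0.322 with divided controls. The signs matched for 80.4% of genes, against 66.7% in the simulations and 73.6% to 77.0% with divided controls.

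**Figure D4:**
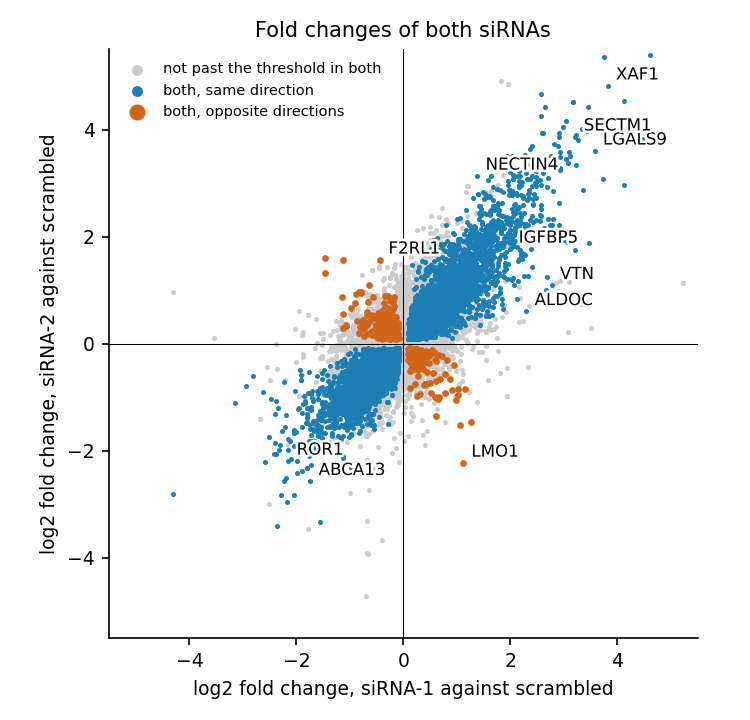
Log2 fold change of each gene with siRNA-1 (horizontal axis) and siRNA-2 (vertical axis), each against scrambled. Blue points passed the threshold in both in the same direction (10118 genes), orange points in opposite directions (434 genes), and grey points did not pass in both. 4 genes lie outside the axes.

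The siRNAs were also compared with each other, since both name the same target. LMO1 differed most, at 11.4 ± 1.09 CPM with siRNA-1 and 1.12 ± 0.11 CPM with siRNA-2, a log2 fold change of -3.35 (SE 0.11, adjusted p = 5.3e-17) for siRNA-2 against siRNA-1. It was raised by siRNA-1 and lowered by siRNA-2 relative to 5.25 ± 0.38 CPM with scrambled siRNA. ALDOC had a log2 fold change of -1.69 (SE 0.12), the adhesion protein gene VTN of -1.68 (SE 0.12), LRRTM1, inside CTNNA2, of -1.67 (SE 0.14) and RPS6KA2-IT1, inside RPS6KA2, of -1.67 (SE 0.12). Higher with siRNA-2 were F2RL1, which encodes a protease-activated receptor (2.00, SE 0.12, adjusted p = 3.65e-12), NECTIN4 (1.75, SE 0.18), the growth factor gene TGFA (1.63, SE 0.17), UST (1.44, SE 0.12) and PAX8-AS1 (1.44, SE 0.13), whose interval lies within that of PAX8. In total 8139 genes differed, 3935 higher and 4204 lower with siRNA-2, and 537 of them at least 2-fold, 366 higher and 171 lower. The groups lay fully apart for 31.9% of genes, where chance gives 2.86%.

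Between the siRNAs 6 lists passed. Cholesterol synthesis genes were lower with siRNA-2 than with siRNA-1, 17 of 22 down and 2 up (camera adjusted p = 1.37e-10, and adjusted p = 0.169 with an estimated correlation). HMGCS1, which encodes HMG-CoA synthase, had a log2 fold change of -0.97 (SE 0.04) and MSMO1 of -0.75 (SE 0.04). Hypoxia and glycolysis genes had 14 of 22 down and 2 up (adjusted p = 1.33e-06, and adjusted p = 0.105 with an estimated correlation), with LDHA, the lactate dehydrogenase A gene, at -0.53 (SE 0.04). p53 target genes had 13 of 22 up and 1 down (adjusted p = 2.11e-04, and adjusted p = 0.722 with an estimated correlation), with XPC at 0.53 (SE 0.04) and BAX at 0.29 (SE 0.05). G2/M and mitosis genes had 11 of 25 up and 0 down (adjusted p = 2.11e-04, and adjusted p = 0.722 with an estimated correlation), with TOP2A at 0.38 (SE 0.04). Type I interferon response genes had 9 of 25 up and 0 down (adjusted p = 3.91e-04, and adjusted p = 0.722 with an estimated correlation), with IFIT2 at 1.06 (SE 0.06). Without scrambled replicate 1, which enters through the shared estimate of spread, 19 of these 25 type I interferon response genes passed. Epithelial marker genes had 3 of 13 down and 1 up (adjusted p = 0.0348, and adjusted p = 0.556 with an estimated correlation), with KRT8 at -0.60 (SE 0.04). The adjusted p of the epithelial marker genes was 0.0704 without siRNA-1 replicate 3 and 0.0746 without siRNA-2 replicate 3. Among genes that overlap no other it was 0.798, and for p53 target genes and type I interferon response genes it was 0.109 and 0.0763.

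The remaining 12 lists did not pass between the siRNAs. Wnt/beta-catenin target genes had 7 of 17 up and 1 down (camera adjusted p = 0.0791), with CD44 at 0.54 (SE 0.04) and DKK1 at 0.48 (SE 0.04). Wnt ligands, receptors and regulators had 9 of 34 up and 12 down (adjusted p = 0.934), with WNT5A at -0.81 (SE 0.04) and WNT7B at 1.14 (SE 0.09). The counts up and down were 6 and 4 of 25 for G1/S and DNA replication genes (adjusted p = 0.934), 5 and 4 of 22 for ATF4 and unfolded protein response genes (0.324), 5 and 1 of 15 for NF-kB and cytokine genes (0.69) and 3 and 6 of 17 for TGF-beta and YAP target genes (0.324). They were 9 and 10 of 26 for extracellular matrix and mesenchymal genes (adjusted p = 0.69), 5 and 3 of 15 for neural stem cell and glial genes (0.934), 4 and 6 of 15 for RNA interference machinery genes (0.324) and 9 and 3 of 22 for apoptosis genes (0.366). Hematopoietic and endothelial marker genes had 1 up and 3 down of 10 (adjusted p = 0.66), and neuron and oligodendrocyte marker genes 1 and 1 of 11 (0.832). Counts adjusted over the list alone differed for 10 of the 18 lists, by at most 3 genes, for example 3 up and 18 down for cholesterol synthesis genes, 15 down for hypoxia and glycolysis genes, 15 up for p53 target genes and 12 up for G2/M and mitosis genes. With an estimated correlation no list passed in any comparison with camera, and its unadjusted p was under 0.05 for 2 lists with siRNA-1, 1 with siRNA-2 and 2 between the siRNAs. With fry, which asks only whether a list's own genes move 1 way, 14, 14 and 10 lists passed. Median and mean differed in sign for 3 lists with siRNA-1 and 2 with siRNA-2, none of which passed with camera. Of these, NF-kB and cytokine genes with siRNA-1 passed with fry (adjusted p = 4.94e-04).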

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

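For the interferon pattern the tests of 1 library, of depth and of a response to the siRNA duplexes were chosen only after the result was seen, and so were the test of the siRNA-1 words between the siRNAs and the refit without both libraries rich in 45S RNA. The tests of full sites were set up after the word scan was seen, before their own values.

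Among 246 groups of 4 libraries for the genes named, a single library lay far from the other 3 in 9, where chance gives about 1 in 20 groups, and in 3 more for measures of the libraries. The measure is the gap to the nearest library over the whole range, compared with Dixon's 95% critical value for 4 libraries. XAF1 (0.878) and ISG20 (0.888) were highest in scrambled replicate 1, LDHA (0.898) highest in scrambled replicate 4, THSD7A (0.935) lowest in scrambled replicate 2 and LCP1 (0.837) lowest in scrambled replicate 4. PRKAR2A (0.832) was highest in siRNA-1 replicate 1, EIF4EBP2 (0.83) and TOP2A (0.876) in siRNA-2 replicate 3, and ADM (0.837) in siRNA-2 replicate 4. Scrambled replicate 1 had reads in 36055 intervals against 31714 to 31828 in the other scrambled libraries (0.974), and 1667 intervals had reads in that library alone against 89 to 176 in each of the others. The 45S share was 15.9% in siRNA-1 replicate 3 against at most 4.18% in the other siRNA-1 libraries (0.836), and siRNA-2 replicate 1 had 42758609 counts against at least 51461698 in the other siRNA-2 libraries (0.856).

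Outside the gene comparisons, 199 of the 481 ultraconserved regions had enough reads to test. With siRNA-1 82 of them passed the threshold, 38 up and 44 down, and with siRNA-2 92, 39 up and 53 down. Of 103 random control regions tested, 29 and 39 passed. Of the 199, 4 are listed as intergenic, and all 4 passed with either siRNA: those that start at 125541790, 125542073 and 125670309 on chromosome 9 fell and lie in the interval of MAPKAP1, and that at 41933165 on chromosome 19 rose. They are named after their values were seen. The others are listed as exonic or intronic, so reads of the regions are in part those of genes.

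Type I interferon response genes were higher with both siRNAs, and 4 technical explanations were set against that. Leaving out any 1 library left at least 0.88 of the median log2 fold change, members that overlap no other gene had at least 1.03 times the median of all members, and mean total counts differed from scrambled by at most a ratio of 1.07. The fold changes are already scaled for library size, so this ratio describes the depth but cannot decide on it as a cause. Only 8% of the members hold a word of the scrambled seed described next. That share bears on direct repression of the members, not on an indirect effect of the scrambled siRNA. Delivery was the same in all groups per the labels, scrambled included. A response to the duplexes of siRNA-1 and siRNA-2 may raise these genes apart from any loss of uc.110, and it cannot be told apart, since beyond scrambled 0 groups received an siRNA against another target or none. A response to loss of uc.110 stays open as well, and so does an indirect effect of the scrambled siRNA in the control libraries.

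Genes with the 7-base word GCAGTAC in the 3' UTR were higher with both siRNAs (t of 14.21 and 12.22, bounds from shuffles 4.64 and 4.88). A candidate explanation is repression by the seed of the scrambled siRNA in the control libraries, which would show as higher levels with either other siRNA. The 218 genes with the full site GCAGTACA exceeded genes with a single word by 7.26 SE with siRNA-1 and 6.51 SE with siRNA-2, and differed from them by -0.25 SE between the siRNAs. Both words of that site, GCAGTAC and CAGTACA, were the most raised words in these same fold changes. Genes with both would thus tend to lie higher in any case, and the excess is no independent test of a seed. With siRNA-1 GCAGTAC also had the larger effect (0.262, 641 genes, against 0.118, 1116 genes). HIPK3 holds GCAGTACA. Direct sites of the scrambled seed do not account for most of the raised genes searched. Of the searched genes up with both siRNAs 14.2% hold either word, against 12.4% of all genes searched. Genes changed indirectly need hold no word, so this share does not bear on them. The siRNA sequence is not given in the sources used here.

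Both siRNAs called 434 genes in opposite directions, LMO1 among them. In siRNA-1 against scrambled, genes with the word AGCCAAA were lowest (t of -7.45, bound 4.64), and between the siRNAs genes with CAGCCAA were highest with siRNA-2 (t of 10.56, against -4.63 for the lowest word), so repression through the siRNA-1 seed may add to the differences. It stays open. Genes with the full site CAGCCAAA differed from those with a single word by 3.21 SE between the siRNAs but by -1.27 SE with siRNA-1. Both words of that site were picked from these same fold changes, so this is no independent test either. CAGCCAAA is held by SH3KBP1 and HADHA, which fell with siRNA-1, but also by NFASC, which rose with siRNA-1. LHX9 holds it too and rose with siRNA-2, which does not bear on the siRNA-1 seed. The siRNA sequence is not known here. Either word is held by 31.5% of the 2392 searched genes higher with siRNA-2, against 23.5% of all genes searched, which leaves most of these genes without a site. For siRNA-2 no word that goes with lower genes passed the bound (lowest t of -4.42), and 6718 genes still differed without both libraries rich in 45S RNA.

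Other splits of the libraries were tested for each count. No other split gave as many genes with siRNA-1 (13318, at most 8 in another split, 1 of 35 as large). Nor did any with siRNA-2 (13988, at most 0, 1 of 35) or between the siRNAs (8139, at most 3, 1 of 35). The same held for the mean of both (14428, at most 2597, 1 of 100). It also held for genes called in the same direction by both (10118, at most 1215, 1 of 100). A random division of these libraries is thus an unlikely source of these counts. A mixed split moves the group difference into the spread, so its low count does not measure calls without a change. A difference between cultures or transfections cannot be excluded this way, since the labels do not say that the libraries of a group came from separate cultures. For the correlation of fold changes (0.806) 4 of 100 splits were as large, a share under 0.05, but another split reached 0.844, so the real grouping does not give the highest value. For the number of lists that passed, a random division cannot be excluded by this count, at 7 with siRNA-1 (at most 9, 5 of 35 as large), 4 with siRNA-2 (at most 6, 9 of 35) and 6 between the siRNAs (at most 7, 8 of 35). Splits that keep 3 libraries of a group together still hold part of the real difference, so they are no reference for no change. Among the 18 splits that mix the groups evenly the highest numbers of lists were 6, 5 and 6, and these are too few for a share under 0.05.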

How the results depend on the processing

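Protein-coding genes only, genes that overlap no other tested gene, and both libraries rich in 45S RNA left out were alternatives chosen after seeing the data. No named gene that passed the threshold in the main fit or in an alternative reversed there, but the balance of higher and lower genes did. A change of sign was not counted where a gene passed in neither fit. With siRNA-1, 7123 genes were higher and 6195 lower, against 6433 and 6485 without a filter on low counts, 6133 and 6236 with 1 CPM in at least 4 libraries, and 4779 and 4865 for protein-coding genes only. The share of called genes that were higher ran from 49.2% to 53.7% with siRNA-1, 49.4% to 53.6% with siRNA-2, 48.6% to 53% for the mean and 46.8% to 51.1% between the siRNAs, and leaving out 1 library was enough to turn it: between the siRNAs it was 4207 higher and 4101 lower without scrambled replicate 1, and with siRNA-1 6340 and 6384 without siRNA-1 replicate 2. With the factors of DESeq2 in edgeR, on the same 24937 genes, siRNA-1 gave 6737 higher and 6535 lower, so a change of scaling alone moved the balance. Whether scaling accounts for the other shifts was not tested. Among genes that overlap no other tested gene, where 8292 genes were tested, fewer were called because fewer were tested: 4199 with siRNA-1, 4561 with siRNA-2, 4685 for the mean of both, 2563 between the siRNAs and 3209 in the same direction, and 3 lists passed between the siRNAs. There 6 lists passed with siRNA-1 and 6 with siRNA-2, with new calls for Wnt ligands, receptors and regulators (adjusted p = 0.0221 and 0.013) and, with siRNA-2, cholesterol synthesis genes (0.0438, lower). Lost there were cholesterol synthesis genes (0.421) and epithelial marker genes (0.628) with siRNA-1, and epithelial marker genes (0.798), p53 target genes (0.109) and type I interferon response genes (0.0763) between the siRNAs. For protein-coding genes only, cholesterol synthesis genes were lost with siRNA-1 (0.0863, 6 lists left) and epithelial marker genes between the siRNAs (0.0997, 5 lists), and without both libraries rich in 45S RNA epithelial marker genes again (0.0692, 5 lists). Without a filter on low counts ATF4 and unfolded protein response genes passed with siRNA-2 (0.0185) and Wnt/beta-catenin target genes between the siRNAs (0.0471). The correlation of fold changes was 0.683 without a filter on low counts (40212 genes) and 0.844 with 1 CPM in at least 4 libraries (19455 genes), and the cause was not tested. With an estimated correlation 0 lists passed with siRNA-1, 0 with siRNA-2 and 0 between the siRNAs, and with fry 14, 14 and 10. Leaving out each library in turn gave 12469 to 13343 genes with siRNA-1, 13173 to 14041 with siRNA-2, 13500 to 14372 for the mean, 7036 to 8308 between the siRNAs, 9375 to 9847 in the same direction, r from 0.778 to 0.816, and 6 to 7, 3 to 4 and 5 to 6 lists. With a replicate block the values were 13215, 13932, 14361, 8053, 10037, an r of 0.807, and 7, 4 and 6 lists. The block was an alternative only, since libraries of the same number had residual correlations of -0.22 to 0.148 (12 pairs, 12473 genes) and those of different numbers -0.251 to 0.213 (36 pairs). DESeq2 gave 12993, 13742, 14203 and 8027 genes, and other scalings shifted the median of all genes by -0.0194 at most. For the 175 genes of the naming rule in the 3 comparisons, 10524 values stayed on their side of the threshold, 170 no longer passed, 49 passed newly and 0 reversed. Calls of lists that depend on 1 library were cholesterol synthesis genes with siRNA-1 (adjusted p = 0.0806 without scrambled replicate 1), extracellular matrix and mesenchymal genes with siRNA-2 (0.0522 without scrambled replicate 1), and epithelial marker genes between the siRNAs (0.0704 without siRNA-1 replicate 3 and 0.0746 without siRNA-2 replicate 3). Depth limits what can be said of uc.110 and MFRP. On simulated data 31 of 50 genes with the smallest planted change were recovered, and 39 of 50 at 1.5-fold. These genes had an average log2 CPM of at least 1, so recovery at the depth of uc.110 and MFRP was not tested.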

Other observations

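The gene families and GBX2 were chosen after their values were seen, or by position, while the test of miR-544 sites was set before its result was seen. The camera p-values of the families come from the same fold changes that led to their choice. Adjusting over the chosen families does not account for that choice, so these p-values describe the families and are no test of them.

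GBX2, a homeobox gene on chromosome 2 from 236165236 to 236168386, is the nearest gene to uc.110 outside LOC105373944. It rose by 0.84 (SE 0.12, edgeR adjusted p = 1.29e-06) with siRNA-1 and by 0.52 (SE 0.12, edgeR adjusted p = 0.00051) with siRNA-2.

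Of 11 aldo-keto reductase genes, which reduce carbonyl compounds, 8 fell with siRNA-1 and 9 with siRNA-2 and none rose (camera adjusted p over 6 families of 6.38e-08 and 3.12e-07, and 0.0437 and 0.0534 with an estimated correlation). AKR1C1 had log2 fold changes of -1.66 and -1.64 and AKR1C2, which shares its reads, of -1.57 and -1.31. Of 80 cytosolic ribosomal protein genes, 67 fell and 2 rose with siRNA-1 (adjusted p = 3.8e-11, and adjusted p = 0.273 with an estimated correlation), and 72 fell and 1 rose with siRNA-2 (2.18e-16, and 0.182 with an estimated correlation). Of 65 histone genes, 29 rose and 4 fell with siRNA-1 (0.00567, and 0.313), and 33 rose and 2 fell with siRNA-2 (2.27e-06, and 0.182). Of 38 keratin genes 22 and 16 rose and 5 and 4 fell (0.00469 and 0.0736, and 0.32 and 0.525 with an estimated correlation), of 11 WNT ligand genes 8 rose and 2 fell with either siRNA (0.0347 and 0.23, and 0.273 and 0.477 with an estimated correlation), and of 36 HOX genes 22 rose and 6 fell with either (0.0334 and 0.0534, and 0.273 and 0.182 with an estimated correlation). KRT81 shares its reads with KRT86, and runs of neighbours have nearly the same values although not all of their intervals overlap (KRT1 and KRT77; KRT3, KRT4, KRT78 and KRT79; KRT6B, KRT6C, KRT75, KRT82 and KRT84; H2AC18 and H2AC19). The 22 raised keratin genes therefore stand for fewer separate signals, which their camera p does not take into account.

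A loss of uc.110 as a sponge of miR-544 could lower genes with a site for miR-544a. The 2283 genes with the seed site TGCAGAA in the 3' UTR had a t of -0.16 with siRNA-1 and -0.55 with siRNA-2, inside the bounds of 4.64 and 4.88, so such a lowering was not seen. A loss of uc.110 itself was not detectable at this depth, and the level of miR-544 was not examined. These values therefore cannot decide whether uc.110 acts as a sponge.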
